A study of Mus musculus with 18 samples.

How the data were processed

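The series holds 18 RNA-seq libraries of mouse bone marrow-derived macrophages in 6 groups of 3. Per the labels' protocols, cells came from mice with a loxP-flanked Eed gene and LysM-Cre (EED KO) or from littermate controls (WT). Unstimulated, LPS primed and LPS tolerant cells were collected from each genotype. Priming used lipopolysaccharide at 100 ng/ml for 24 h, and tolerant cells were then rested for 48 h and given LPS again at 10 ng/ml, per the labels' protocols. The duration of the second LPS exposure, and whether primed cells were rested before collection, are not given in the sources used here. Libraries were stranded, made from mRNA, and read as pairs of 150 bp, per the labels' protocols. The labels do not say whether replicate numbers stand for separate mice, so the p-values measure the spread between these samples, which may be partly technical. For 1 library, WT LPS primed replicate 1, the labels lack the description that ties the other libraries to a comparison. Whether it entered the authors' LPS primed comparison is therefore open.

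The submitters' processing notes name HISAT2, edgeR, R 4.0.3 and the genome build GRCm39. How these were combined, the gene annotation, the filters and the test within edgeR are not given in the sources used here. The authors deposited 1 list of genes with higher and 1 with lower expression per condition. Each deposited row holds a gene symbol, an Ensembl identifier, a log fold change, an unadjusted p-value and an adjusted p-value. The log2 scale is an assumption: per the file headers, the deposited fold change is a log value whose base is not stated. The direction of the contrast is not stated either. It was read as EED KO against WT because Eed is in the lower list of each condition. Normalised values or counts per library were not used here, so the depth behind each value is unknown. No model was fitted, and no replicate was left out in turn. All fold changes and p-values printed for genes are copied from the authors' deposited table.

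The deposited rows show bounds of the selection but not its full rule. Unadjusted p-values reached 0.0497, 0.0497 and 0.0498 in unstimulated, LPS primed and LPS tolerant cells, and absolute log2 fold changes started at 0.75 in each. The authors' lists were therefore counted as deposited, and the rows with an adjusted p-value under 0.05 were counted separately; this second count was added after the data had been seen. Words such as rose and fell are kept for the latter rows. The number of tests behind each adjusted p-value was recovered from the ratio of adjusted to unadjusted p, which under the Benjamini-Hochberg procedure is a whole number of tests divided by a rank. It came to 413233, 379717 and 338297, and 69.4%, 60.5% and 60.3% of the usable rows then had ranks that were whole to within 1e-06. The GENCODE vM21 annotation of GRCm38, an older build than the authors', holds 55450 genes, 141767 transcripts and 446235 distinct exons. A deposited row can thus stand for a part of a gene, and its fold change need not hold for the whole transcript. At an adjusted p under 0.05, ranks reached at least 271, 1109 and 837, against 44, 125 and 99 listed genes, so most tests past that threshold have no listed row of their own. If no test held a true difference, 20662, 18986 and 16915 tests would be expected under an unadjusted p of 0.05.

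That recovery was tested on simulated tables, where it returned the true number in 20 of 20. Both its settings and the way the simulated p-values were drawn were changed over several rounds until it did. Earlier rounds with other settings missed the true number in most simulated tables, so 20 of 20 is not an independent rate of success. The recovered number is the smallest whole number that the rows allow, and a multiple of it cannot be ruled out. For the gene-list tests, simulations on the 377 genes of the LPS primed list found the planted list in 100 of 100 runs with each test. The list planted for the direction test held mostly lower genes. These runs therefore do not show that a short list of higher genes would be found among mostly higher genes. Of 1900 random lists, 34 were called at an unadjusted p under 0.05 by the direction test and 4 of 1900 by the test between conditions. The 1900 can include lists with too few members to be tested, so these are not rates per test run. Genes of a random list need not move together, as genes of a real list can. The low counts therefore do not vouch for the tests on real lists.

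Standard errors were not part of the deposited columns. An approximate standard error was taken as the absolute log2 fold change divided by the normal quantile of its p-value, a choice made after the data had been seen. It served to compare the fold changes of genes listed in 2 conditions, with a two-sided normal test and Benjamini-Hochberg adjustment within each pair of conditions. It assumes independent libraries and the same gene part in both lists.

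Lists were compared between conditions by gene symbol, leaving out symbols listed in both directions in 1 condition. Overlap in each direction was tested with a one-sided hypergeometric test in a universe of 12000 genes, which is an assumption. Agreement of direction among shared genes was tested with a two-sided Fisher's exact test. Pearson's r and Spearman's rho across shared genes describe the lists, since genes are not independent replicates and were selected for size in both. The 95% intervals of r came from 2000 bootstrap draws of genes. The libraries of the 3 comparisons differ, though the same mice may have given cells to all conditions.

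The design, the alternatives, 33 gene lists and the rule for naming genes were fixed before the data were examined. Each list with at least 3 listed members was tested for direction against the other listed genes of that condition, and for membership of genes listed in only 1 of 2 conditions. Both were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over lists. Counts adjusted over the list alone set every unlisted member to a p of 1. They count 1 test per gene, although a row can stand for 1 of several parts of a gene, so they can be too lenient. Named genes were, per condition and direction, the 8 with the largest absolute fold change outside predicted genes and the 4 with the smallest adjusted p. Eed and other listed subunits of its complex, up to 4 members of each gene list per condition, and the 8 genes per direction with the largest mean change among those listed in all 3 conditions were added. The result of 1 gene list and of a gene that the rule names is not reported here. A gene named outside this rule is said to be so where it appears. Older symbols were matched through the RefSeq annotation of GRCm38.p6, and 219, 360 and 406 of the 220, 360 and 406 identifiers in the 3 conditions were found in GENCODE vM21. No coordinates are printed, because the authors' build differs. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

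Alternatives were adjusted p under 0.01 and under 0.001, absolute log2 fold changes of at least 1 and at least 2, lists without predicted genes, and universes of 10000, 15000 and 20000 genes. Adjusted p under 0.05, and rows with identical values counted once, were added after the data had been seen. Another normalisation, other filters on low values, another pseudocount, a replicate block and leaving out replicates all need values per library and were not run.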

Results

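EED is a core subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3 and keeps target genes silent. The series asked how its loss alters macrophages that have been made tolerant to lipopolysaccharide (LPS), a bacterial cell wall component. LPS tolerance is the muted response of macrophages to a repeated LPS dose. Gene expression was measured by RNA-seq in mouse bone marrow-derived macrophages, which are primary cells grown from marrow. Deletion of Eed used LysM-Cre, a Cre recombinase inserted in the Lyz2 gene. There were 6 groups of 3 libraries: EED KO and WT cells, each unstimulated, LPS primed (100 ng/ml for 24 h) and LPS tolerant (primed, rested for 48 h and given 10 ng/ml). The values come from the authors' deposited table of genes per condition, so the depth of each library is unknown. Fold changes are EED KO against WT, on a log scale whose base was taken as 2.

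Eed was the only listed member of the 13 PRC2 subunits in each condition, and it was lower in EED KO cells in all 3. The authors' deposited table gives it a log2 fold change of -3.04 in unstimulated cells (8.23-fold lower, approximate implied SE 0.26, adjusted p = 1.44e-25). In LPS primed and LPS tolerant cells the authors' deposited table gives Eed values of -3.59 (adjusted p = 1.46e-32) and -3.87 (adjusted p = 9.42e-24). These rows can stand for a part of Eed, the deleted part included, so the values need not hold for the whole transcript. Lyz2, the lysozyme gene that carries the Cre insertion, also fell, by 1.17, 1.19 and 0.93 on the log2 scale in the same order, in the authors' deposited table. Its neighbour Lyz1 fell by 1.86 and 1.71 in unstimulated and LPS primed cells in the authors' deposited table, and stood at -2.92 (adjusted p = 0.246) in tolerant cells. Reads of these near-identical lysozyme genes can be hard to assign. Whether the Cre insertion lowers Lyz2 apart from the loss of Eed was not tested. The Lyz2 values therefore cannot be read as an effect of Eed loss alone.

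**Figure D1:**
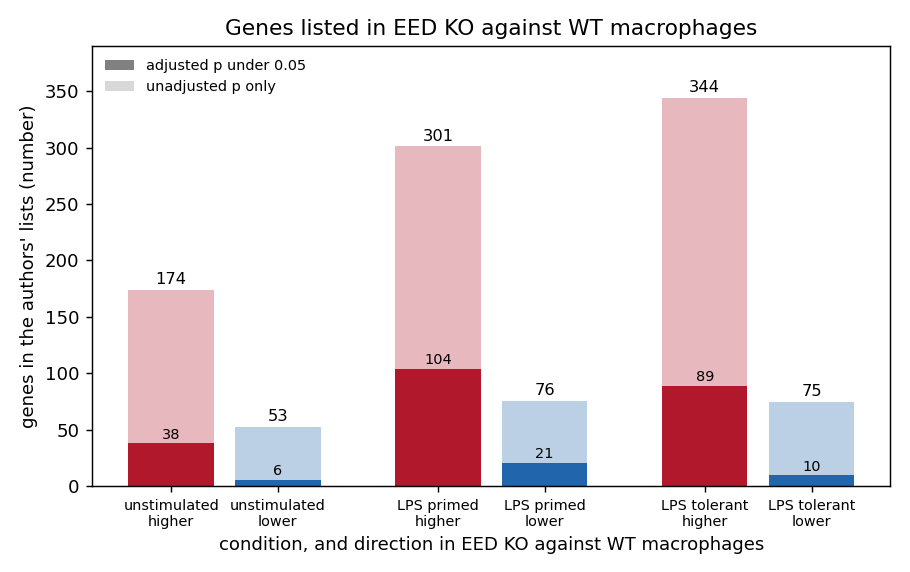
Number of genes in the authors' deposited lists by condition and direction in EED KO against WT macrophages. Full colour marks genes with an adjusted p under 0.05 and pale colour the remaining listed genes. Higher genes outnumber lower genes in each condition, 174 to 53, 301 to 76 and 344 to 75.

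In unstimulated macrophages, most listed genes were higher in EED KO cells. Of the 227 listed genes, 174 were higher and 53 lower in EED KO cells, and 38 rose and 6 fell at an adjusted p under 0.05. These 44 listed genes compare with at least 271 tests past that threshold, each possibly of a part of a gene. Serpine2, a secreted protease inhibitor, rose by 4.29 (SE 0.48) and Clstn1, a cell-surface protein of the cadherin superfamily, by 2.97 (SE 0.34) on the log2 scale in the authors' deposited table. Bmpr1a, a receptor for bone morphogenetic proteins, rose by 2.39 and the cadherin Fat3 by 2.21 in the authors' deposited table. Cdkn2a, which encodes cell cycle inhibitors and is a classical Polycomb target, rose by 2.69 (SE 0.57, adjusted p = 0.00722) in the authors' deposited table. It was the only listed gene of 8 cyclin-dependent kinase inhibitors, and none of the 8 was listed in LPS primed or LPS tolerant cells. Ly6c1 had the largest change, 7.51 with an SE of 1.42, in the authors' deposited table, and belongs to a family of similar genes.

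Genes of MHC class II, which present peptides to T cells, were among those that rose. In the antigen presentation list of 31 genes, 5 were listed, 4 higher and 1 lower, and 3 rose. H2-Ab1, H2-Eb1 and H2-Aa rose by 1.63, 1.69 and 1.51 in the authors' deposited table, with adjusted p of 0.000544, 0.000563 and 0.038. Cd74, the invariant chain that escorts class II molecules, stood at 1.10 (adjusted p = 1) in the authors' deposited table. Adjusted over the list alone, 3 of these genes passed. Here and below, that adjustment counts 1 test per gene, although a row can stand for a part of a gene, so it can be too lenient. Markers of other cells that carry class II were listed beside them, Ighm of B cells at 1.63 (adjusted p = 0.132) and Cd24a of dendritic cells at 0.93 (adjusted p = 0.573) in the authors' deposited table, and each passed when adjusted over its list alone. Bmi1, a subunit of the companion complex PRC1, rose by 1.19 (adjusted p = 0.0104) in the authors' deposited table and was the only listed gene of 20 in its list.

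Few genes fell in unstimulated cells. Ctsk, a collagen-degrading protease of osteoclasts, fell by 1.89 (adjusted p = 0.000238) in the authors' deposited table, and the predicted gene Gm7592 fell by 3.67. Of 25 pro-inflammatory cytokines and mediators, only Ptgs2, the inducible cyclooxygenase, was listed, at -1.13 with an adjusted p of 1 in the authors' deposited table. Of 29 chemokines, Cxcl2 stood at -1.43 and Cxcl14 at 1.07 in the authors' deposited table, both with an adjusted p of 1. Il1rn, from the list of 38 LPS-tolerance and negative regulators, stood at -0.99 (adjusted p = 0.63) in the authors' deposited table.

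Other lists that had listed genes in unstimulated cells held 1 to 4 each, with few past the adjusted threshold. Ccnd2, the only listed gene of 47 in cell cycle and proliferation, stood at 2.12 (adjusted p = 0.121) in the authors' deposited table and passed when adjusted over its list alone. Extracellular matrix genes were represented by Col4a1 at 1.43, Col4a2 at 1.00 and Mmp13 at 0.83 in the authors' deposited table, and none of the 3 passed; adjusted over the list alone, 2 did. Irf4, Mrc1 and Gas6, from the alternative activation list, stood at 0.95, 1.24 and 0.78 in the authors' deposited table with adjusted p of 1. Cd34, a progenitor marker, stood at 1.84 (adjusted p = 0.153) in the authors' deposited table and passed when adjusted over its list alone. Of the stress genes, Egr3 stood at 1.56, Hspa1b at -0.77 and Hspa1a at -0.82 in the authors' deposited table, with adjusted p of 0.22 or more; adjusted over the list alone, all 3 passed. Listed genes of the lipid, glycolytic and core macrophage lists included Scd1 at 1.43, Pkm at 2.08 and C1qa at 1.19 in the authors' deposited table, each with an adjusted p of 1. Of 4 listed interferon-stimulated genes, 3 were lower, Slfn1 at -1.06, Ms4a4c at -0.88 and Apol9b at -1.40, and Iigp1 was higher at 1.08, none past the adjusted threshold, in the authors' deposited table. The direction test found no list among 6 that differed from the other listed genes after adjustment, and 1 at an unadjusted p under 0.05 (interferon-stimulated genes, p = 0.0406, adjusted p = 0.243, two-sided Fisher's exact test). In 93 of the 227 rows the adjusted p was 1.

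In LPS primed macrophages the lists were longer. Of 377 listed genes, 301 were higher and 76 lower, and 104 rose and 21 fell at an adjusted p under 0.05. Cxcl13, a chemokine that attracts B cells, rose by 5.46 (43.9-fold, SE 0.37, adjusted p = 1.5e-42) in the authors' deposited table. The clotting factor subunit F13a1 rose by 3.40, the gelatinase Mmp9 by 3.43 and the apolipoprotein Apoe by 3.31 in the authors' deposited table. Kcnn3, a potassium channel, and Fam171b rose by 5.13 and 4.28 in the authors' deposited table. Cx3cr1, the fractalkine receptor, rose by 2.24 and Ccnd2, a G1 cyclin, by 2.22 in the authors' deposited table.

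Class II genes were again among those that rose in LPS primed cells. All 4 listed genes of the antigen presentation list were higher, and 3 rose, with H2-Aa at 1.70, H2-Eb1 at 1.52 and Cd74 at 1.14 in the authors' deposited table. H2-Ab1 stood at 1.09 (adjusted p = 0.189) in the authors' deposited table. Adjusted over the list alone, all 4 passed. Fscn1, an actin-bundling protein of mature dendritic cells, rose beside them by 2.58 (adjusted p = 8.49e-12) in the authors' deposited table. Peg10 and Dcn, from the list of imprinted genes, rose by 3.36 and 1.71 in the authors' deposited table. Both listed PRC1 subunits rose, Bmi1 by 0.83 and Cbx6 by 1.34, in the authors' deposited table.

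Interferon-stimulated genes formed the largest listed group in LPS primed cells. Of 75 such genes, 19 were listed and all 19 were higher, with a median log2 fold change of 1.25 among the listed genes, computed from the authors' deposited table. Gbp5, a guanylate-binding protein of host defence, rose by 1.36 (adjusted p = 0.000119) and Ly6c2, a monocyte surface marker, by 2.01 (adjusted p = 0.00941) in the authors' deposited table. The other 17 did not pass, among them Gbp7 at 0.98 (adjusted p = 0.0592) and Gbp2 at 1.09 (adjusted p = 0.116) in the authors' deposited table. Adjusted over the list alone, 9 passed. Their direction did not differ from that of the other listed genes after adjustment over 9 lists (p = 0.018, adjusted p = 0.162, two-sided Fisher's exact test), and no other list passed at an unadjusted p under 0.05. Gbp3 and Gbp4, and Tgtp1 and Tgtp2, share 1 Ensembl identifier per pair in the deposited rows, so they are not separate measurements beyond doubt. The sex-linked Xist and Tsix were also listed in LPS primed cells, at 0.83 (adjusted p = 0.846) and 0.78 (adjusted p = 0.637) in the authors' deposited table.

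Among chemokines, 6 of 29 were listed in LPS primed cells and 2 rose, Cxcl13 and Cxcl14, the latter by 1.57 in the authors' deposited table. Ccl6 stood at -1.13 (adjusted p = 0.0828) and Ccl12 at 1.73 (adjusted p = 0.47) in the authors' deposited table. Marco, a scavenger receptor for bacteria, rose by 1.29 (adjusted p = 6.22e-05) in the authors' deposited table. Mcemp1, from the neutrophil list, fell by 1.09 in the authors' deposited table. Dcn is also a stromal marker and Mmp9 an osteoclast marker, and Eng, from the endothelial and epithelial list, stood at 0.86 (adjusted p = 0.0559) in the authors' deposited table. Of the extracellular matrix list, 5 genes were listed, all higher, and 2 rose, Mmp9 and Mmp13, the latter by 1.62 in the authors' deposited table. Il7r, the interleukin-7 receptor, fell by 1.18 (adjusted p = 0.0419) in the authors' deposited table. H2-Q1, a nonclassical class I gene, had the most negative value, -9.45 with an SE of 1.73, in the authors' deposited table. Dusp4, Egln3, Wnt6 and Gclm stood at -0.90, 0.93, 1.07 and -0.78 in the authors' deposited table, with adjusted p of 0.0532 or more.

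In LPS tolerant macrophages, again, most listed genes were higher in EED KO cells. Of 419 rows, 344 were higher and 75 lower, and 89 rose and 10 fell at an adjusted p under 0.05. Cxcl13 rose by 4.59 (24.1-fold, SE 0.34, adjusted p = 4.19e-37) in the authors' deposited table. F13a1, Mmp9 and Cx3cr1 rose by 3.40, 3.41 and 1.87 in the authors' deposited table. Cd209f, a C-type lectin, rose by 7.07 (SE 0.86) and Tle2, a transcriptional corepressor, by 5.38 (SE 0.48) in the authors' deposited table. The guanylate-binding proteins Gbp2b and Gbp10, outside the interferon list fixed in advance, rose by 4.22 and 3.43 in the authors' deposited table.

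Chemokines were the best represented inflammatory list in tolerant cells. Of 29, 8 were listed, 6 higher and 2 lower, and 4 rose; adjusted over the list alone, 6 passed. Besides Cxcl13, the platelet chemokine Ppbp rose by 2.03, the monocyte attractant Ccl8 by 1.46 and Cxcl14 by 1.84 in the authors' deposited table. Cxcl1, named outside the rule, was among the lower ones, at -0.89 in tolerant and -0.81 in primed cells in the authors' deposited table. It passed the adjusted threshold in neither. Il1f9, which encodes interleukin-36 gamma, rose by 1.78 (adjusted p = 2.03e-06) in the authors' deposited table and was the only listed gene of 25 pro-inflammatory cytokines and mediators. No gene of the LPS-tolerance and negative regulator list was listed in tolerant cells. The collagenase Mmp8 rose by 1.30, Car2, a carbonic anhydrase, by 1.82, and the oxidative stress gene Nqo1 by 1.77 in the authors' deposited table. Some of the chemokine and matrix genes that rose also stand in marker lists of other cell types, as the same measurements. Mmp8 was the only listed gene of 22 neutrophil markers. Ppbp and Car2 were the 2 listed of 24 erythroid, megakaryocyte and progenitor markers, and Mmp9 and Car2 the 2 listed of 12 osteoclast markers. Of these, only Car2 is in neither the chemokine nor the matrix list. Fscn1, of the dendritic cell list, rose by 1.30 (adjusted p = 0.00149) in the authors' deposited table, and Igfbp7, a stromal marker, stood at 1.12 (adjusted p = 0.12). Both listed hypoxia-responsive genes rose, Ndrg1 by 1.53 and Egln3 by 1.45, in the authors' deposited table.

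Class II genes were listed in tolerant cells without passing the adjusted threshold. All 5 listed antigen presentation genes were higher, H2-Ab1 at 0.96 (adjusted p = 0.122), H2-Eb1 at 0.94 (adjusted p = 0.227) and H2-Aa at 0.80 (adjusted p = 0.521) among them in the authors' deposited table. Adjusted over the list alone, all 5 passed. Only 3 of 75 interferon-stimulated genes were listed, all higher and none past the threshold, with Ly6e at 1.04 and Ly6c2 at 1.49 in the authors' deposited table. Peg10 rose by 2.26 (adjusted p = 0.00787) in the authors' deposited table. Bmi1 stood at 0.97 (adjusted p = 0.114) and Dcn, also a stromal marker, at 1.35 (adjusted p = 0.668) in the authors' deposited table. Cd36, a lipid scavenger receptor, rose by 0.92 (adjusted p = 0.0479) and Gas6, a ligand for engulfment receptors, by 1.16 (adjusted p = 0.0251) in the authors' deposited table.

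Genes that fell in tolerant cells were few. H2-Q1 had the most negative value, -13.12 with an SE of 0.58, in the authors' deposited table. Il7r fell by 1.38, Tmtc2 by 1.31 and Atp5j, an ATP synthase subunit, by 1.25 in the authors' deposited table. The antimicrobial list held 7 listed genes of 35, 4 higher and 3 lower, and only Lyz2, which carries the Cre insertion, fell. Lcn2 stood at 0.87 (adjusted p = 0.201) and Saa2 at -2.21 (adjusted p = 1) in the authors' deposited table. The direction test found no list among 10 that differed from the other listed genes, before or after adjustment (smallest adjusted p = 0.721, two-sided Fisher's exact test). Since most listed genes were higher, a short list with all members higher could not pass. The antigen presentation list, with 5 higher and 0 lower, had an unadjusted p of 0.592 in the same test. Hox genes, the Toll-like receptor pathway and mast cell, basophil and eosinophil markers had no listed gene in the 3 conditions. H2-K2 and H2-Q2 were each listed as both higher and lower in tolerant cells, so a symbol can stand for more than 1 measurement. H2-Q and H2-K genes are near-identical copies that vary between strains, and values for them, H2-Q1 included, are uncertain. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 belong to the same H2 gene complex. Whether a strain difference there bears on their values in any condition was not tested.

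**Figure D2:**
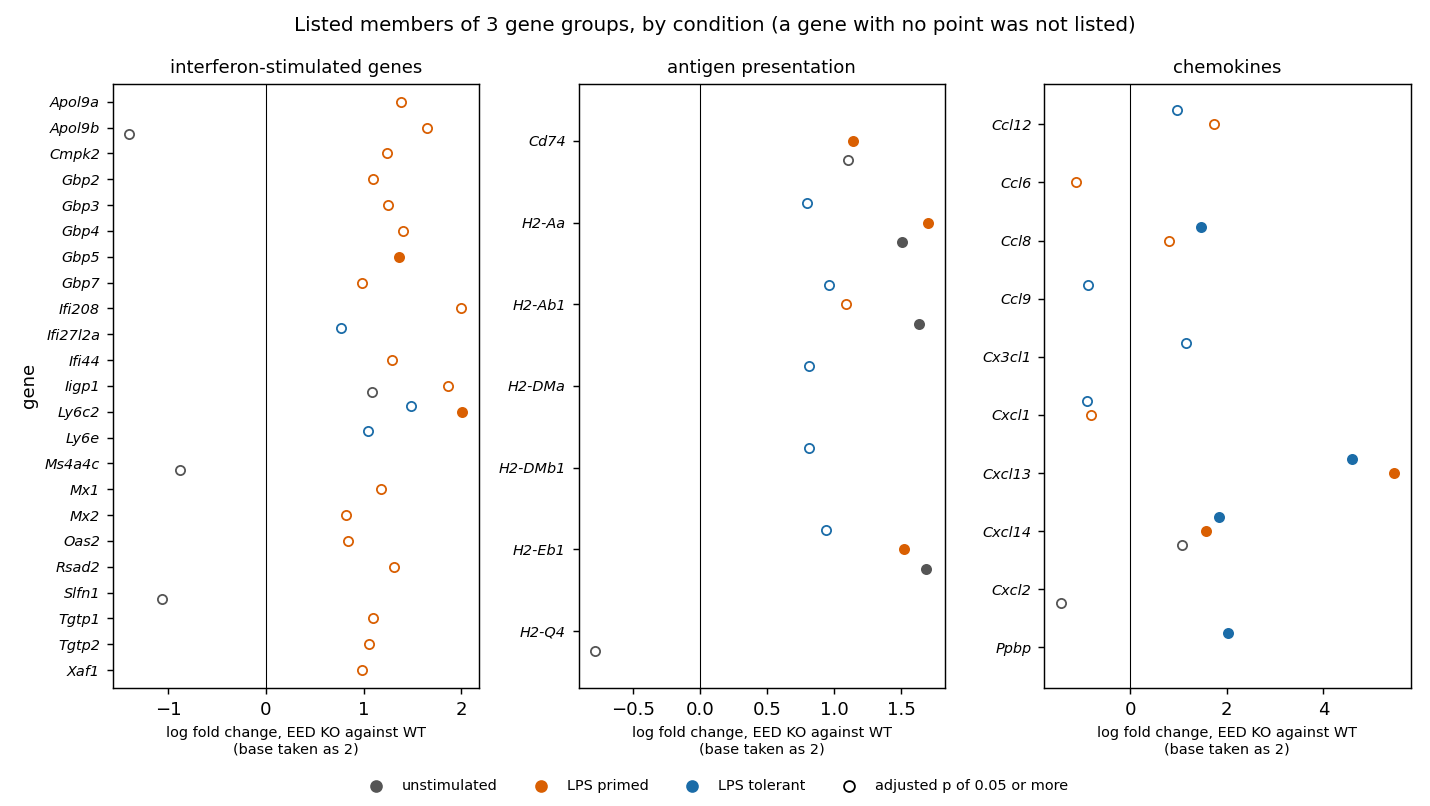
Log fold changes (EED KO against WT, base taken as 2) from the authors' deposited table for listed members of 3 gene lists, coloured by condition. Filled points have an adjusted p under 0.05, open points do not, and a gene with no point in a condition was not listed there. The 19 interferon-stimulated genes listed in LPS primed cells are all to the right of 0.

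Interferon-stimulated genes were listed more often in primed than in tolerant cells. They made up 18 of the 264 genes listed in LPS primed but not tolerant cells (6.82%), against 2 of 304 in tolerant but not primed cells (0.658%; p = 4.97e-05, adjusted p = 0.000547 over 11 lists, two-sided Fisher's exact test). Compared with unstimulated cells, 17 were listed only in primed and 2 only in unstimulated cells, the 17 higher and the 2 lower in EED KO cells, which did not pass (p = 0.0438, adjusted p = 0.526 over 12 lists, two-sided Fisher's exact test). No other list differed between conditions at an adjusted p under 0.05. With genes restricted to an adjusted p under 0.05, 2 interferon-stimulated genes were left in primed cells, too few to test, and no list differed. The test compares membership of lists and does not show that the fold changes of these genes differ between conditions. It covers the fixed list only: the guanylate-binding proteins Gbp2b and Gbp10, which rose in tolerant cells, are outside it.

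The same genes recurred across conditions more often than lists drawn with equal chances for every gene would give. Unstimulated and LPS primed cells shared 57 higher genes, against 4.36 by chance in the assumed universe, and 12 lower genes, Eed included as in each pair, against 0.336 (one-sided exact hypergeometric p = 8.45e-49 and 3.65e-16). Unstimulated and tolerant cells shared 43 higher and 13 lower genes (4.96 and 0.322 by chance, exact hypergeometric p = 1.2e-28 and 3.53e-18). Primed and tolerant cells shared 90 higher and 14 lower genes (8.58 and 0.462 by chance, exact hypergeometric p = 9.37e-69 and 1.31e-17). Direction agreed for 69 of 73, 56 of 58 and 104 of 111 shared genes in these pairs (two-sided Fisher's exact p = 3.07e-10, 6.08e-11 and 8.79e-12). Across shared genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.728 (95% interval 0.575 to 0.886), 0.727 (0.534 to 0.911) and 0.822 (0.496 to 0.938), with Spearman's rho of 0.712, 0.72 and 0.631. The same mice may have given cells to all conditions, so the lists are not independent beyond doubt. A gene tested in more parts can also have more chances to be listed in each condition. The overlap test does not account for that, and it treats genes as independent, so its p-values can be too small.

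In all 3 conditions, 38 genes were listed in the same direction, 30 higher and 8 lower. At an adjusted p under 0.05 in every condition there were 8, of which 6 rose: Bmpr1a, Clstn1, Cd55, Igf2bp3, Kctd17 and Plxdc2. Those that fell were Eed, the deleted gene, and Lyz2, which carries the Cre insertion. Igf2bp3, Kctd17 and Plxdc2 lie outside the naming rule and were named after their values had been seen. Bmpr1a rose by 2.39, 2.83 and 2.61 in unstimulated, primed and tolerant cells in the authors' deposited table. Cd55, which shields cells from complement, rose by 1.99, 2.22 and 1.71 in the authors' deposited table. Of 816 symbols listed in any condition, 135, 232 and 285 were listed only in unstimulated, primed and tolerant cells. Being listed in 1 condition alone does not show that the effect differs from that in another.

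**Figure D3:**
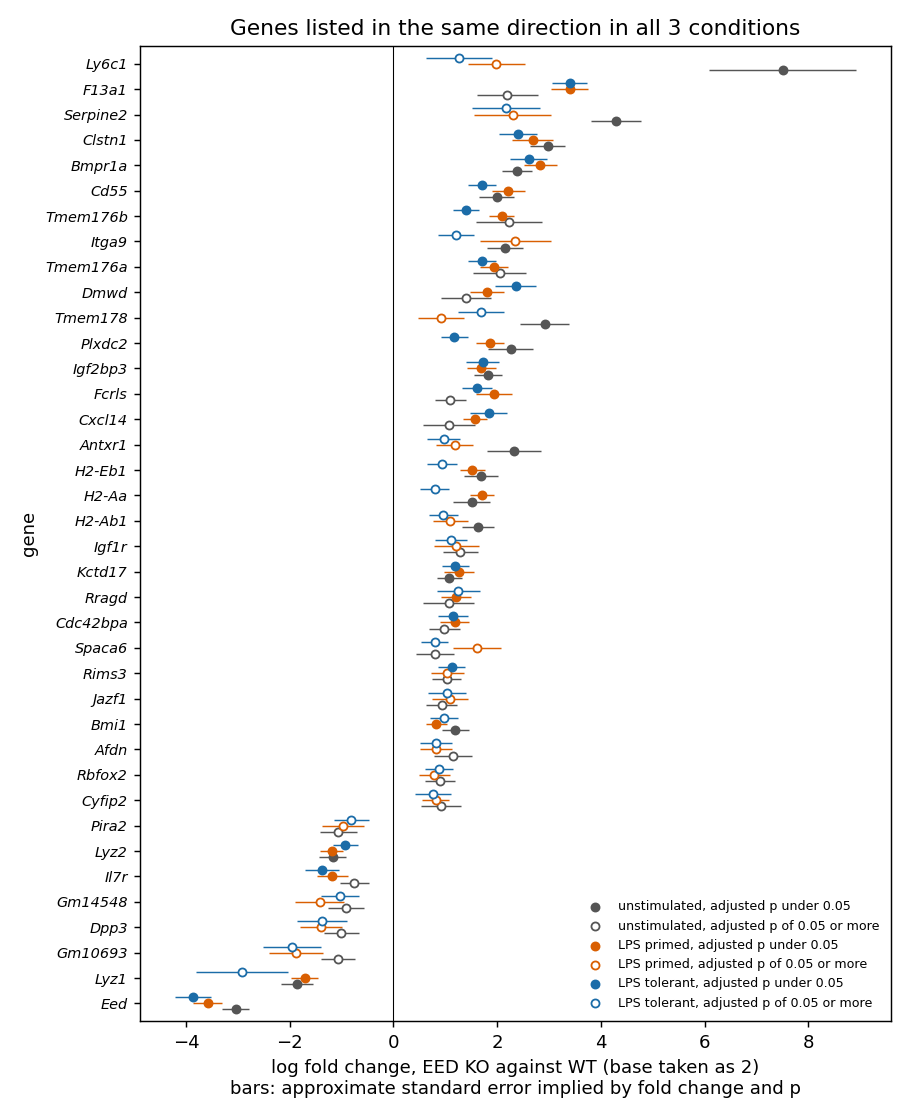
Log fold changes (EED KO against WT, base taken as 2) of the 38 genes listed in the same direction in all 3 conditions, from the authors' deposited table. Bars are approximate standard errors implied by each fold change and its p, and filled points have an adjusted p under 0.05. Eed has the lowest values, from -3.04 to -3.87, and 30 genes are above 0 in each condition.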

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

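The test of each difference below was chosen after the fold changes had been seen, and it uses approximate standard errors implied by the authors' deposited table. Of 73, 58 and 111 genes shared by unstimulated and LPS primed, unstimulated and tolerant, and primed and tolerant cells, 6, 3 and 8 differed between conditions at a Benjamini-Hochberg adjusted p under 0.05. All 13 cases of a gene listed in opposite directions (12 genes, Gm2427 in 2 pairs) are among these 17, which follows almost by construction, since each passed an unadjusted p under 0.05 on both sides of 0. None of the 13 had an adjusted p under 0.05 in both conditions, and the rows of 1 symbol can come from different parts of a gene. Differences are given as the log2 fold change in the condition named second minus that in the condition named first.

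Ly6c1 was listed as higher in EED KO cells in all 3 conditions, but passed the adjusted threshold only in unstimulated cells (adjusted p = 0.088 in primed cells). Its difference was -5.53 from unstimulated to primed cells and -6.25 from unstimulated to tolerant cells in the authors' deposited table. Both rest on an unstimulated value of 7.51 with an SE of 1.42. Tmem178 differed by -2.004 from unstimulated to primed cells and Fscn1 by -1.28 from primed to tolerant cells, both with the same direction in each condition, from the authors' deposited table. From unstimulated to primed cells, the genes with opposite directions were H2-Q10 (2.68), Apol9b (3.05), Slc28a2 (1.85) and Ermard (-2.39), from the authors' deposited table. Tuba1a (3.21) and Gm2427 (-2.9999) had opposite directions in unstimulated and tolerant cells in the authors' deposited table. Between primed and tolerant cells, opposite directions were listed for Tle2 (6.33), Gm10499 (2.59), Gclm (1.57), Gm2427 (-2.82), Mndal (-2.98), Mtus1 (-2.65) and Saa2 (-4.16) in the authors' deposited table. Genes here that fall outside the naming rule were named because they passed this test.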

How the results depend on the processing

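Counts of adjusted p under 0.05, and of identical rows counted once, were added after the data had been seen. The number of listed genes depended on the threshold, by construction. In the order unstimulated, LPS primed and LPS tolerant, the lists held 44, 125 and 99 genes at an adjusted p under 0.05, 29, 86 and 76 under 0.01, and 23, 58 and 56 under 0.001. Absolute log2 fold changes of at least 1 left 136, 205 and 167 genes, and of at least 2 left 24, 37 and 36. Higher genes stayed in the majority, at 76.7% to 86.4%, 79.8% to 91.4% and 81.2% to 96.4% of the genes under these settings, without predicted genes and with identical rows counted once.

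Shared genes with the same direction, in the order unstimulated and primed, unstimulated and tolerant, primed and tolerant, numbered 14, 10 and 37 at an adjusted p under 0.05 in both lists, 8, 8 and 29 under 0.01, and 8, 7 and 10 at an absolute log2 fold change of at least 2. The overlap of higher genes exceeded that of equal chances for every gene in each universe, at an adjusted p under 0.01, at a log2 fold change of at least 2 and without predicted genes. Lower overlaps include the deleted gene and Lyz2, which carries the Cre insertion. Without Eed, a choice made after the data had been seen, 11, 12 and 13 lower genes were shared (exact hypergeometric p = 1.31e-14, 1.42e-16 and 3.96e-16). Without Eed and Lyz2, chosen likewise, 10, 11 and 12 were shared (exact hypergeometric p = 4.42e-13, 5.47e-15 and 1.14e-14). At an adjusted p under 0.01 or a log2 fold change of at least 2, either choice left only 0 or 1 per pair, too few to read. Pearson's r of shared genes moved to 0.988, 0.957 and 0.974 at an adjusted p under 0.05 and to 0.99, 0.957 and 0.979 under 0.01, with fewer genes in each. No list passed the direction test at an adjusted p under 0.05 or 0.01, at a log2 fold change of at least 2, without predicted genes or with identical rows counted once. The difference between primed and tolerant cells in interferon-stimulated genes was found without predicted genes and with identical rows counted once. At an adjusted p under 0.05, under 0.01, and at a log2 fold change of at least 2, 0 lists differed between conditions, with fewer genes tested.

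No paired analysis was possible because values per library were not used here; EED KO and WT share replicate numbers 1 and 3 only. Leaving out replicates, another normalisation, a pseudocount, filters on low values and a filter on mean expression were not run for the same reason. What depth limits is unknown.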

Other observations

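The lists hold fewer independent measurements than rows, with 5 sets of rows that carry identical values. In tolerant cells, 24 rows of the protocadherin gamma cluster, which shares its last exons among many adhesion genes, carry 1 log2 fold change of 0.83 (adjusted p = 0.665) in the authors' deposited table. Ang and Rnase4, which share a promoter and first exons, likewise carry 1 value of -1.01 (adjusted p = 0.0513) in the authors' deposited table. These genes were named after their values had been seen. Among rows with an adjusted p of 1, 120 of 155 were higher in EED KO cells (77.4%), close to the share among all listed rows. The excess of higher genes thus also appears in rows without support after adjustment. Whether the listing rule or the normalisation contributes to it was not tested.

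The tests in the following paragraphs were chosen after the result had been seen, except that of linkage and the tests of gene lists between conditions; the latter were fixed before the data were examined, and only their use here was decided afterwards. Adjusted p-values were large for the p-values beside them. The nearest multiplier of a Benjamini-Yekutieli adjustment over genes missed by up to 4.69. The recovery kept only whole numbers, which such multipliers rarely are, so the miss alone cannot decide against that adjustment. Under the Benjamini-Hochberg procedure, at least 338297 tests were implied in each condition, more than the genes and transcripts of GENCODE vM21. Tests on parts of genes such as exons could give such a number. Whether the adjusted p-values of whole genes would be smaller was not tested. No biological explanation was tested.

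Genes lower in EED KO cells in at least 2 conditions held many members of multigene families. Among 21 such genes other than Eed and Lyz2, 10 belonged to families such as H2-Q, Pira, Sirpb1, Lyz and predicted genes, against 5 of 130 higher in at least 2 conditions (two-sided Fisher's exact p = 5.83e-07). Only 1 of the 21, Lyz1, lay within 10 Mb of Eed or Lyz2 in GRCm38, so linkage over that distance cannot account for most of them. Among genes lower in 1 condition it was 2 of 142 (p = 0.341, two-sided Fisher's exact test). With so few genes near the loci, that test cannot decide whether linkage adds to the recurrent genes. Linkage over longer distances was not tested. The families were chosen after the lower genes had been seen, so their p decides nothing, and strain differences in family copies, reads shared between copies and an effect of EED all stay open.

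Interferon-stimulated genes were listed mainly in LPS primed cells. The primed list is shorter than the tolerant list (377 against 419 rows), so a longer list does not account for the contrast with tolerant cells. The primed list held more rows past the adjusted threshold, though (125 against 99). Whether a stronger primed comparison contributes was not tested. Against the shorter unstimulated list (227 rows), length cannot be told apart (adjusted p = 0.526, two-sided Fisher's exact test). Chance among unadjusted p-values cannot be told apart: all 19 were higher (two-sided exact binomial p = 3.81e-06 against an even split), but rows with an adjusted p of 1 also lean to higher, and genes driven by 1 signal can move together in a single culture. A different sex composition of the cultures cannot be told apart either, although of 6 sex-linked genes only Xist, at 0.83 in the authors' deposited table, and Tsix were listed and none of the 4 Y-linked ones; the limit of 2 written for this test was too high, because groups that mix both sexes in different shares would give a smaller value. An effect of EED on the interferon response to LPS stays open and was not tested.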
